A study of Mus musculus with 12 samples.

How the data were processed

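Gene expression was measured in mouse embryonic stem (ES) cells on 12 Agilent 2-colour arrays, each carrying 45018 spots, of which 43379 were not controls. Per the labels, the RNAs were 1 wild-type ES cell RNA and, for each of 2 Dicer-null clones (27G5 and 27H10), RNA of the Dicer-null cells, of the same cells overexpressing Dnmt1, and of the same cells overexpressing Dnmt3a and Dnmt3b. The labels do not say whether an RNA of one name was 1 extract on all of its arrays; each name was taken as 1 RNA, which makes 7 RNAs. Per the labels, the cells grew on gelatin-coated plates with leukemia inhibitory factor, the growth description names no feeder layer, and RNA Integrity Numbers lay between 8.0 and 9.5. Each array held 2 RNAs, and each pairing was hybridised 2 times with the dyes exchanged. The 12 arrays therefore gave 6 ratios: Dicer-null over wild type, Dnmt1 over Dicer-null, and Dnmt3a and Dnmt3b over Dicer-null, each in both clones.

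The scanner files held the mean signal intensity and the median background intensity of each spot per the file headers, which name Agilent Feature Extraction 9.5.1.1 for the 8 arrays with RNA labelled as overexpressing (overexpression arrays) and 9.1.3.1 for the 4 arrays with wild-type RNA. The deposited files also held a log10 ratio of the background-subtracted, dye-normalised signals of each array. The series value table deposited by the authors was on the log2 scale and turned so that its sign gave the first-named cells over their reference. Its columns correlated with the scanner log ratio, put on the log2 scale and turned in the same way, at r = 0.968 to 1.00 across probes, with slopes near 1. The medians of its columns were -0.13, 0.17, -0.02 and 0.13 in clone 27G5 and -0.11, 0.14, -0.14 and 0.12 in clone 27H10 for the overexpression arrays, and -0.13, -0.10, 0.11 and -0.02 for the arrays with wild-type RNA. No per-sample column was left unused (0 columns).

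The main values were computed from the intensities in R 4.3.3 with limma 3.58.1 and statmod 1.5.0. Background was corrected with the normexp method (offset 50), and ratios were normalised by loess within each array. Spots of one probe were averaged, dye-swapped arrays were turned to one direction, and the 2 arrays of a pair were averaged, since they held the same 2 RNAs. The chip had 41174 distinct probes, of which 22951 were named through a RefSeq accession and 18223 kept the name in the array design; 29253 carried a gene symbol. Symbols followed the mouse annotation on assembly GRCm38.p6, which served for names alone, while probe positions are on build mm7 (NCBI35), as the headers of the overexpression arrays give them. A gene was tested when a probe was present on all 12 arrays and was well above background, by the scanner software, on both arrays of at least 1 of the 7 RNAs in the channel that held it. Its value was that of the probe with the highest mean signal, which left 20063 genes. Other probes of a gene could differ: of 116 named gene results with more than 1 probe, 52 had log2 ratios more than 2 times apart or of opposite sign, 15 of them of opposite sign.

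The 6 ratios were fitted together with lmFit, with 1 coefficient for each of the 3 comparisons, which left 3 residual degrees of freedom, and tested with eBayes in limma. The Dnmt3a and Dnmt3b coefficient was also compared with the Dnmt1 coefficient. A gene was called at an adjusted p (Benjamini-Hochberg over all genes tested) under 0.05. The replicate unit was the clone (n = 2), and SD is the standard deviation over the 2 clones. Because the labels name no separate cultures, p measures the spread between these samples. The wild-type cells were 1 control RNA, so their own spread is left out of p. Where a channel was not well above background on any of its arrays, the fold is a lower bound, with that channel raised to its lowest signal well above background, and is written "at least". The number of arrays limits the precision of every value.

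The groups, the tests, the rule for named genes, the 21 gene lists and all alternatives but 5 were chosen before the data were examined. The named genes were Dicer1, Dnmt1, Dnmt3a, Dnmt3b and Rbl2; for each comparison with a reference, the 10 highest and the 10 lowest genes with a symbol among those called with the same sign on all 4 arrays; 5 in each direction for the comparison of the conditions labelled as overexpressing; and, of each list, up to 4 members with the largest moderated statistic. Of the 448 list entries, 422 were measured, standing for 407 distinct genes. The lists held DNA methylation machinery, retinoblastoma family and G1/S regulators, published miR-290 cluster targets, published let-7 targets, small RNA machinery, pluripotency genes, primitive endoderm, mesoderm, neuroectoderm, trophoblast and fibroblast markers, germline genes silenced by DNA methylation, imprinted genes, 2-cell-stage genes, telomere maintenance, heterochromatin and Polycomb regulators, p53 targets, interferon response and MHC class I, glycolysis and hypoxia, DNA replication and mitosis, and ribosomal proteins. Each list was tested against all other genes with camera (preset correlation 0.01), adjusted over the 63 tests, and again with camera with an estimated correlation and with fry, which asks whether the genes of a list move one way on balance and compares them with no other genes. None of the 15 calls held with an estimated correlation (0 calls). That version takes p from the 3 residual degrees of freedom, so few lists could pass over 63 tests. Imprinted genes over wild type, with an estimated correlation of -0.007, went from an unadjusted camera p of 0.000621 to 0.0311. For imprinted genes the lost call therefore does not show that correlation between genes produced it. Estimated correlations of the other called lists were higher, from 0.01 for miR-290 targets to 0.25 for trophoblast markers and 0.51 for p53 targets. In lists with a high value, correlation between genes may have contributed to the calls, which the 3 residual degrees of freedom do not separate.

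With each name taken as 1 RNA, the comparisons share RNAs: both ratios of a clone against Dicer-null cells have 1 denominator, that RNA is the numerator over wild type, and both ratios over wild type share the wild-type RNA. If the extracts differed, less would be shared than the fit with shared RNAs and the simulation assume. Correlations between comparisons were therefore computed across clones, where the ratios share no RNA. They run across genes, and genes are not independent replicates, so they carry no p. What shared RNAs alone give was simulated in 20 draws without any effect.

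The fit was tested on simulated data with 200 changed genes among 20063. It recovered 26.9%, 82.1% and 95.5% of log2 changes of 0.5, 1 and 2 for Dicer-null over wild type, 17.9%, 82.1% and 98.5% for Dnmt1, and 13.4%, 77.6% and 95.5% for Dnmt3a and Dnmt3b. Of its calls, 33.7%, 14.8% and 15.6% were of unchanged genes. The data gave far more calls than 200, and such shares depend on how many genes change, so they do not carry over to the data. A fit that modelled the shared RNAs called unchanged genes in 4.67%, 7.03% and 4.96% of its calls, and fits to single arrays in 62.7% to 81.4%. The simulated data had the covariance that the fit with shared RNAs assumes, so its low shares were set by the construction. Simulated signs were never wrong (0 calls).

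Alternatives were no background correction, the deposited log ratios, median centring, scaling between arrays, the series value table, looser and stricter filters on dim probes, the mean over probes, each comparison fitted alone, shared RNAs modelled, an intensity trend with robust variances, single arrays with and without a dye term (replicate block), slide as a block, a minimum log2 ratio of 1, and leaving out each ratio in turn. The dye term is the dye orientation, which the replicate number also gives. Added after the data were seen were a fit without 1 array of the dye-swapped pair whose arrays matched least, slide as a fixed block, the filters and the mean over probes applied to the correlations and to the gene lists, and the left-out ratios applied to the gene lists. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.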

Results

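Mouse embryonic stem (ES) cells lacking Dicer, the nuclease that makes microRNAs, were compared with wild-type ES cells. Dicer-null cells labelled as overexpressing the DNA methyltransferases Dnmt1, or Dnmt3a and Dnmt3b, were compared with their Dicer-null parents. Each of the 6 ratios came from 2 dye-swapped arrays. Each comparison had 1 ratio from clone 27G5 and 1 from clone 27H10, so every value below is a mean log2 ratio ± SD over clones (n = 2). The median signal of an array was 112 to 135 in the green and 234 to 334 in the red channel, and 61.7% to 68.4% of probes in green and 64.2% to 68.7% in red were well above background. Adjusted p values are from limma over 20063 genes. The overexpression arrays of clone 27G5 were on 1 slide, those of clone 27H10 on another, and the arrays with wild-type RNA on the third. Slide and clone cannot be told apart in the overexpression comparisons, although each ratio lies within an array.

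The first comparison asked which genes differ when Dicer is missing. Dicer1 itself was lower at both of its probes on chromosome 12 (build mm7): at the brighter probe (102216485 to 102216544, minus strand) by -0.53 ± 0.04 (adjusted p = 0.0040), and at the second (102186776 to 102188847) by -4.07 ± 0.08. The call at the brighter probe was lost under 3 of 19 alternatives, among them leaving out the 27H10 ratio. The labels do not say which part of the gene is deleted. Of 2-cell-stage genes, Zscan4c, a regulator of telomeres in ES cells, rose by 3.46 in clone 27G5 and 3.18 in clone 27H10, and Usp17la rose by 2.69 ± 0.25. Rbl2, a retinoblastoma-family repressor and published target of the miR-290 cluster, rose by 1.85 ± 0.03 (adjusted p = 0.000218; 1.29 ± 0.02 at its second probe). The pluripotency factors Tbx3 and Nanog rose by 1.73 ± 0.15 (0.53 at its second probe) and 1.45 ± 0.26, while the actin-binding protein Tagln and the collagen Col1a1 fell by -4.20 ± 0.13 and -4.09 ± 0.13.

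The highest genes in Dicer-null cells were Dglucy, a glutamate cyclase, at 4.19 ± 0.07, and Msln, encoding the surface protein mesothelin, at 3.98 ± 0.15. Next came Ube1y1, a Y-linked ubiquitin-activating enzyme gene, at 3.76 ± 0.24, Smc1b, a meiotic cohesin subunit, at 3.74 ± 0.55, and Serpinc1, encoding antithrombin, at 3.70 ± 0.08. Y-linked genes were looked at as a group after these values were seen. Of 12 measured, Ube1y1 among them, 6 rose and none fell (0), with a median of 0.50 (0.46 to 1.03 over the scalings; unadjusted camera p = 0.00191, but 0.127 with an estimated correlation). Since Ube1y1 prompted the choice and stayed in the group, that p partly restates its rise. Kdm5d, a histone demethylase, rose by 2.02 ± 0.09 (1.86 to 3.58 over the scalings), and Eif2s3y, at 0.58 ± 0.13, did not pass. Wdfy4 rose by 3.52 ± 0.60, the renin gene Ren2 by 3.45 ± 0.46, the lipoxygenase Alox12e by 3.45 ± 0.01, the tetraspanin Tspan1 by 3.42 ± 0.02 and the adhesion receptor Adgrg6 by 3.39 ± 0.13. Second probes were lower for Serpinc1, at 0.94, and for Adgrg6, at 0.42. The lowest gene was the serine protease Prss23, at -5.46 ± 0.10 (adjusted p = 4.53e-05). Slc39a8, a zinc transporter, was at least 24.7-fold lower and not well above background in Dicer-null cells (0 of 4 arrays), while its second probe was at -2.05. The smooth-muscle calponin Cnn1 fell by -4.38 ± 0.09, the tubulin regulator Stmn4 by -4.01 ± 0.04, the galectin Lgals1 by -3.50 ± 0.05, the acyltransferase Mogat2 by -3.47 ± 0.21, Aif1l by -3.45 ± 0.09 and trophinin, Tro, by -3.40 ± 0.34 (its 4 probes ranged from -3.43 to -0.65). Among the fixed genes, Dnmt3b (chromosome 2, 153428204 to 153428263) fell by -1.23 ± 0.30 (adjusted p = 0.0107; 0.121 without the 27G5, 0.0594 without the 27H10 ratio and 0.292 with shared RNAs modelled). Neither Dnmt1 (chromosome 9), at 0.29 ± 0.04 (adjusted p = 0.0635), nor Dnmt3a (chromosome 12), at -0.88 ± 0.24 (adjusted p = 0.0883), passed, and the other Dnmt3a probes gave 0.15 ± 0.07 and -0.72 ± 0.13. Under the alternatives Dnmt1 passed in 1 and Dnmt3a in 6, with adjusted p from 0.00349 to 0.416 for Dnmt3a.

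**Figure D1:**
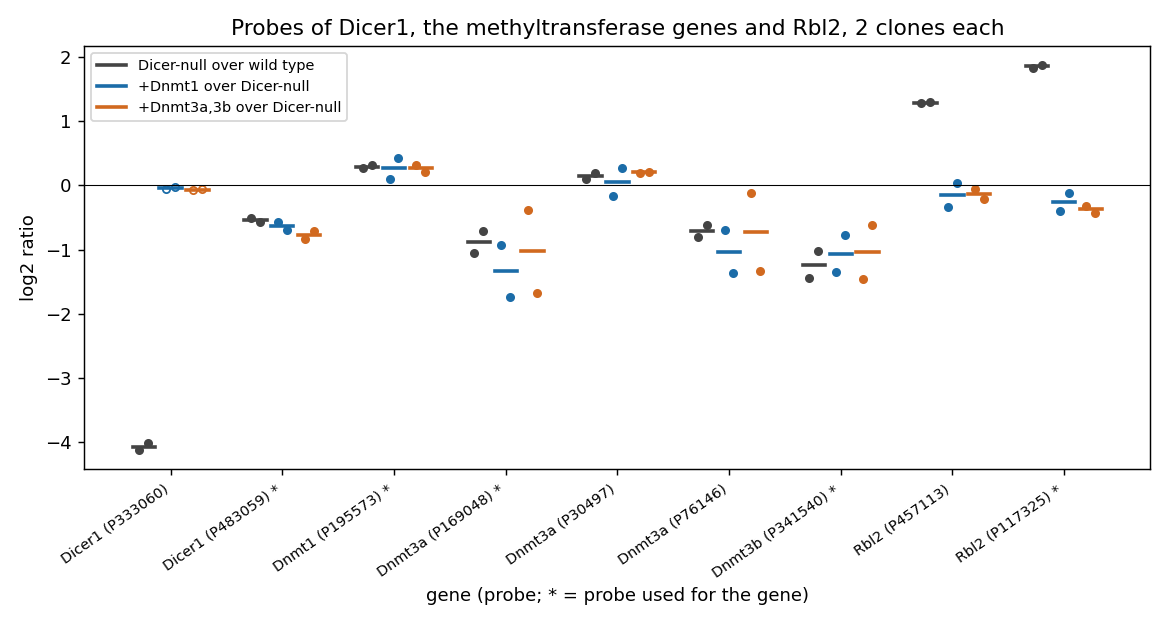
Log2 ratios of every probe of Dicer1, Dnmt1, Dnmt3a, Dnmt3b and Rbl2 in the comparisons with a reference; points are the 2 clones, bars their mean, asterisks the probe used, and hollow points stand for probes not well above background in either channel on any of the arrays. The Dicer1 probes lie at -0.53 and -4.07 over wild type, and no methyltransferase probe reaches a log2 ratio of 1 in the cells labelled as overexpressing it.

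Of the 21 gene lists, 6 passed camera over wild type. Among 2-cell-stage genes, 9 of 10 rose, 0 fell and 1 did not pass (9 rose when adjusted over the list alone). The median was 1.57 (adjusted p = 0.000649; adjusted p = 0.716 with an estimated correlation), and 0.90 without the 27G5 ratio. The members Tcstv1 and Pramel7 rose by 2.25 ± 0.23 (probes from 1.34 to 2.25) and 2.18 ± 1.61. Among pluripotency genes, 12 of 23 rose, 1 fell and 10 did not pass, as when adjusted over the list alone. The median was 0.62 (adjusted p = 0.00374; adjusted p = 0.716 with an estimated correlation). Nr0b1 rose by 1.24 ± 0.17 and Gdf3 by 1.30 ± 0.28, Pou5f1 was at 0.32 without passing, and the RNA-binding protein Lin28a fell by -3.24 ± 0.03. Among published targets of the miR-290 cluster, microRNAs abundant in ES cells, 10 of 14 rose, 3 fell and 1 did not pass, as when adjusted over the list alone. The median was 0.83 (adjusted p = 0.0248; adjusted p = 0.716 with an estimated correlation). Lefty1, a Nodal inhibitor, rose by 1.97 ± 0.08, Ei24, an apoptosis-related gene, by 1.61 ± 0.11, and Cdkn1a, the cell-cycle inhibitor p21, by 1.32 ± 0.28, while the Wnt inhibitor Dkk1 fell by -1.31 ± 0.15.

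Fibroblast markers fell: 13 of 21 were lower, 2 higher and 6 did not pass (14 lower and 2 higher when adjusted over the list alone). The median was -0.68 (adjusted p = 0.000253; adjusted p = 0.716 with an estimated correlation). Col1a2 fell by -2.34 ± 0.09 and S100a4 by -1.98 ± 0.09, whereas Dcn, which encodes the matrix proteoglycan decorin, rose by 2.02 ± 0.28 and the transcription factor Twist1 by 0.54 ± 0.19. The probes of Col1a1 differed, with values from -4.09 to 0.01. Imprinted genes fell beside these markers: 15 of 27 were lower, 3 higher and 9 did not pass (15 and 4 when adjusted over the list alone). The median was -0.72 (adjusted p = 0.00435; adjusted p = 0.716 with an estimated correlation). The growth factor Igf2 fell by -2.69 ± 0.45, the growth-restraining Phlda2 by -2.79 ± 0.15, Magel2 by -2.69 ± 0.01 and the cell-cycle inhibitor Cdkn1c by -2.66 ± 0.11, and Plagl1 rose by 2.46 ± 0.23. Trophoblast markers also fell beside the fibroblast markers, with 7 of 12 lower, 1 higher and 4 not passing, as when adjusted over the list alone. The median was -0.68 (adjusted p = 0.00639; adjusted p = 0.762 with an estimated correlation). The keratins Krt7 and Krt18 fell by -2.35 ± 0.14 and -2.14 ± 0.06. Krt18 was saturated in the wild-type channel, so its fall may be larger than measured. The trophectoderm regulator Cdx2 fell by -2.10 ± 0.43 (-3.86 to -1.93 over the scalings), while Elf5 rose by 0.79 ± 0.12.

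The other 15 lists did not pass camera, although single members changed. With fry, 4 of these passed: mesoderm (median -0.47, adjusted p = 0.00867), small RNA machinery (median 0.22, 0.0119), primitive endoderm (median -0.33, 0.0144) and let-7 targets (median -0.21, 0.0468). Dicer1, the gene these cells lack, is on the small RNA machinery and let-7 lists and is counted among the members that fell. The fry result of the let-7 targets thus partly restates the loss of Dicer. Of interferon and MHC class I genes, 7 of 24 rose and 5 fell (7 and 7 when adjusted over the list alone; adjusted p = 0.827): Oas1a, a sensor of double-stranded RNA, rose by 2.28 ± 0.08 and Irf9 by 1.83 ± 0.00, and Isg15 fell by -1.48 ± 0.12. Of mesoderm markers, 3 of 14 rose and 7 fell, as when adjusted over the list alone (adjusted p = 0.168). Brachyury, T, was at -2.46 ± 0.01 (-4.18 to -2.27 over the scalings), Wnt3 at -2.06 ± 0.02 (-3.03 at its second probe) and Kdr at 1.67 ± 0.14 (0.01 at its second probe). Of primitive endoderm markers, 3 of 19 rose and 9 fell, as when adjusted over the list alone (adjusted p = 0.0944; 0.0303 without the 27G5 ratio and 0.0297 with the stricter filter on dim probes), with Dab2 at -2.20 ± 0.21 and Amn at -1.25 ± 0.02. Of small RNA machinery genes, 9 of 20 rose and 4 fell (9 and 5 when adjusted over the list alone; adjusted p = 0.324), with the helicase Mov10 at 1.90 ± 0.09 and the Argonaute partner Tnrc6a at 0.92 ± 0.03 (its 3 probes ranged from 0.48 to 0.92). Of germline genes, 6 of 24 rose and 3 fell, as when adjusted over the list alone (adjusted p = 0.474), with meiotic Stra8 at 1.49 ± 0.05, and Tdrd1, of the piRNA pathway, at -2.10 ± 0.11 (-0.42 at its second probe).

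Of retinoblastoma family and G1/S regulators, 9 of 27 rose and 8 fell, as when adjusted over the list alone (adjusted p = 0.747), with E2f8 at -1.06 ± 0.08 (-0.13 at its second probe) and cyclin D1, Ccnd1, at -0.67 ± 0.05. Of let-7 targets, 4 of 15 rose and 5 fell (4 and 6 when adjusted over the list alone; adjusted p = 0.445). Their median was -0.21 and their mean -0.32. Igf2bp2 was at 1.22 ± 0.06 and Plagl2 at 1.02 ± 0.07, while Lin28a and Dicer1, which fell as given above, are also on this list. Of the DNA methylation machinery, 5 of 20 rose and 6 fell (6 and 6 when adjusted over the list alone; adjusted p = 0.761), with the glycosylase Tdg at -1.20 ± 0.12 and the dioxygenase Tet2 at 0.56 ± 0.04. Of neuroectoderm markers, 5 of 14 rose and 3 fell (6 and 4 when adjusted over the list alone; adjusted p = 0.713), with Fgf5, a marker of the primed epiblast, at -2.39 ± 0.36. Of p53 targets, 6 of 21 rose and 5 fell, as when adjusted over the list alone (adjusted p = 0.855), with Rrm2b at 1.35 ± 0.02 (1.24 to 2.08 over the scalings) and Zmat3 at -0.90 ± 0.04. Of heterochromatin and Polycomb regulators, 3 of 17 rose and 3 fell, as when adjusted over the list alone (adjusted p = 0.855), with the methyltransferase Suv39h1 at -1.39 ± 0.08. Of telomere genes, 6 of 28 rose and 5 fell, as when adjusted over the list alone (adjusted p = 0.855), with Nop10 at -0.72 ± 0.10. Of glycolysis and hypoxia genes, 5 of 21 rose and 4 fell, as when adjusted over the list alone (adjusted p = 0.891), with Ndrg1 at 1.62 ± 0.28 and hexokinase, Hk1, at 1.30 ± 0.03 (its 5 probes ranged from 0.19 to 1.30). Of replication and mitosis genes, 4 of 25 rose and 0 fell (1 and 0 when adjusted over the list alone; adjusted p = 0.304), with Ccnb2 at 0.50 ± 0.03. None of 25 ribosomal protein genes changed (0 rose and 0 fell, also when adjusted over the list alone; adjusted p = 0.713); their median was 0.05 and -0.10 with median centring. Medians and means differed in sign for neuroectoderm (0.18 and -0.04), telomere (-0.04 and 0.01) and interferon genes (-0.01 and 0.15, camera upward).

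In total 8111 genes passed over wild type, 4084 higher and 4027 lower, of which 1122 and 992 changed at least 2-fold. Of these calls, 7961 had 1 sign on all 4 arrays, and the clones correlated at r = 0.938 across genes. Both ratios share the wild-type RNA, so a part of this likeness and of the shared signs can come from it. That RNA alone gave a correlation of 0.492 in simulation without any effect, which cannot be set beside 0.938 to size that part. A fit that models the shared RNAs called 1945 of these genes, and 3482 or 3121 genes passed without the 27G5 or the 27H10 ratio.

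The second comparison asked what differs in Dicer-null cells labelled as overexpressing Dnmt1. Among the genes that rose most were prolactin-family hormones of the placenta: Prl2a1, Prl2c5, Prl2c3 and Prl3d2 rose by 4.99 ± 0.26, 4.59 ± 0.37, 4.46 ± 0.48 and 3.80 ± 0.22. The Dicer-null signals of Prl2a1 and Prl2c3 were well above background on 2 of 4 arrays and that of Prl3d2 on 3, and the 3 probes of Prl2c3 ranged from 1.81 to 4.46. Gata3, a transcription factor of trophoblast, rose by 3.01 ± 0.73 and the homeobox gene Rhox6 by 3.75 ± 0.25. Fgf5, a marker of the primed epiblast, and the homeobox gene Otx2 fell by -1.64 ± 0.65 and -1.24 ± 0.43. Dnmt1 was at 0.27 ± 0.23 (adjusted p = 0.111), so its signal was not called higher in the cells labelled as overexpressing it. Of the alternatives, 1 called it higher, that without the 27G5 ratio (0.43, adjusted p = 0.0390), and without the 27H10 ratio it was at 0.10 (adjusted p = 0.541).

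Sct, encoding the hormone secretin, rose by 4.10 ± 0.58 and Shroom1 by 3.14 ± 1.49. The genes that fell most were Alox12e, at -3.07 ± 0.36, the fatty acid desaturases Scd2 and Scd1, at -2.75 ± 0.74 and -2.23 ± 0.14, the endothelin Edn2, at -2.59 ± 0.49, and the lysine-degrading Aass, at -2.46 ± 0.92. They were followed by Dcn at -2.45 ± 0.06 (-4.40 to -2.35 over the scalings), the kallikrein Klk1b5 at -2.37 ± 0.33, Nsg2 at -2.36 ± 0.10, the Nodal inhibitor Lefty2 at -2.28 ± 0.36 and Ucma at -2.23 ± 0.47. Among the fixed genes, Dicer1 fell by -0.63 ± 0.09 (adjusted p = 0.00675; a call lost under 3 of 19 alternatives) at the brighter probe, the other being not well above background (0 arrays). Dnmt3a fell by -1.34 ± 0.58 (adjusted p = 0.0406; its other probes gave 0.05 and -1.04) and Dnmt3b by -1.06 ± 0.40 (adjusted p = 0.0309). These calls were lost under 4 and 5 alternatives, among them leaving out the 27H10 ratio (adjusted p = 0.229 and 0.0605) and, for Dnmt3b, the 27G5 ratio (0.139). Rbl2, at -0.26 ± 0.21, did not pass (adjusted p = 0.104).

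Trophoblast markers rose as a group: 8 of 12 were higher, 0 lower and 4 did not pass (9 higher when adjusted over the list alone). The median was 1.46 (adjusted p = 3.43e-06; adjusted p = 0.716 with an estimated correlation). Krt7 rose by 2.81 ± 0.30, Csh1, the array's name for placental lactogen Prl3d1, by 2.49 ± 0.01, Krt18 by 2.13 ± 0.45 and Tfap2c by 1.75 ± 0.15. The stem-cell regulators Cdx2, Elf5 and Eomes, at 0.53, 0.22 and 0.09, did not pass. Among germline genes silenced by DNA methylation, 9 of 24 rose, 0 fell and 15 did not pass, as when adjusted over the list alone. The median was 0.46 (adjusted p = 0.000756; adjusted p = 0.716 with an estimated correlation), and 0.31 without the 27G5 ratio. Rhox9 rose by 2.92 ± 0.11, the testis transcription factor Taf7l by 1.92 ± 0.42 and the meiosis gene Stra8 by 1.57 ± 0.18. Rhox5 and Rhox6, of the same family as Rhox9, were also among the members that rose. Of interferon and MHC class I genes, 8 of 24 rose, 1 fell and 15 did not pass (11 and 1 when adjusted over the list alone). The median was 0.37 (adjusted p = 0.00445; adjusted p = 0.827 with an estimated correlation), 0.66 without the 27G5 and 0.22 without the 27H10 ratio. Oasl1 rose by 1.41 ± 0.28, Isg15 by 1.14 ± 0.03 and the immunoproteasome subunit Psmb8 by 1.03 ± 0.49, and Usp18 was at least 2.03-fold higher.

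Neuroectoderm markers fell: 8 of 14 were lower, 1 higher and 5 did not pass, as when adjusted over the list alone. The median was -0.64 (adjusted p = 0.0167; adjusted p = 0.716 with an estimated correlation). The neuronal microtubule protein Map2 fell by -1.40 ± 0.21 and Gbx2 by -1.27 ± 0.53, while Pax6 rose by 1.23 ± 0.18. Of p53 targets, 5 of 21 fell, 1 rose and 15 did not pass (5 and 2 when adjusted over the list alone). The median was -0.35 (adjusted p = 0.0131; adjusted p = 0.897 with an estimated correlation). That call was lost with fry (adjusted p = 0.188) and without the 27H10 ratio (median -0.07, adjusted p = 0.415), while the median was -0.59 without the 27G5 ratio. Zmat3 fell by -0.51 ± 0.05 and Perp by -0.65 ± 0.42. Fibroblast markers, 3 higher, 3 lower and 15 not passing, as when adjusted over the list alone, did not pass camera (median -0.03, but 0.02 to 0.03 with median centring and the deposited values; adjusted p = 0.747). Of imprinted genes, 7 of 27 rose and 4 fell (8 and 4 when adjusted over the list alone; adjusted p = 0.424, but 0.0279 with fry), among them Cdkn1c at 2.11 ± 0.54, Sgce at 2.04 ± 0.34, the noncoding H19 at 2.00 ± 0.08 (3.06 at its second probe) and Igf2 at 1.47 ± 0.28. The glycolysis list (2 of 21 rose, as when adjusted over the list alone; adjusted p = 0.239) had a median of 0.13. It passed without the 27G5 ratio (0.25, adjusted p = 0.00369) and turned to -0.03 without the 27H10 ratio (adjusted p = 0.747). Its member Slc2a3, a glucose transporter, rose by 0.95 ± 0.09 (0.14 at its second probe).

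The other 13 lists, none of which passed camera, held further single changes. With fry, primitive endoderm markers (adjusted p = 0.0365) and let-7 targets (0.0409) passed. The let-7 targets that fell include Dicer1, whose value is given above. Basement-membrane collagens of the primitive endoderm list rose (Col4a2 1.27 ± 0.08, Col4a1 1.23 ± 0.38; 6 of 19 higher and 3 lower, as when adjusted over the list alone). Of heterochromatin and Polycomb regulators, 1 of 17 rose, Suv39h1, by 1.02 ± 0.27, and 2 fell, as when adjusted over the list alone. Their median was -0.12 (adjusted p = 0.198), and -0.18 with median centring (adjusted p = 0.0498). The telomere-associated Rif1 fell by -0.98 ± 0.05 and the dyskerin gene Dkc1 by -0.78 ± 0.24, with 6 of 28 telomere genes lower and 1 higher, as when adjusted over the list alone (adjusted p = 0.443). Among let-7 targets, Lin28a fell by -0.96 ± 0.15, and Hmga2, a chromatin protein, by -1.09 in clone 27G5 and -0.90 in clone 27H10, with its weakest probe at -0.46. Of pluripotency genes, 4 of 23 rose and 3 fell (4 and 4 when adjusted over the list alone; adjusted p = 0.912), with Nanog at 0.68 ± 0.36 and Nr5a2 at -0.99 ± 0.44. Of 2-cell-stage genes, Tcstv1 and Tcstv3 rose by 0.97 ± 0.17 and 0.95 ± 0.13 and 8 did not pass (adjusted p = 0.799). Of the miR-290 targets, 3 of 14 rose and 3 fell (4 and 4 when adjusted over the list alone; adjusted p = 0.827), with Lefty1 at -1.09 ± 0.38. Of replication and mitosis genes, 1 of 25 rose and 2 fell (0 and 2 when adjusted over the list alone), with a median of -0.06 (adjusted p = 0.362) that passed at -0.15 with median centring (adjusted p = 0.0166). The ribosomal protein list (1 of 25 fell; adjusted p = 0.747) had a median of 0.04 that became -0.11 with median centring (adjusted p = 0.0424). Of Y-linked genes, 9 of 12 fell and 0 rose, with a median of -0.67 (-1.45 to -0.64 over the scalings; unadjusted camera p = 8.27e-07, and 0.0446 with an estimated correlation). This group was chosen after the data were seen, so its unadjusted p values cannot be set beside the adjusted ones of the lists. The median and mean differed in sign for 2-cell-stage (0.09 and -0.03), mesoderm (0.02 and -0.05), miR-290 (0.20 and -0.08) and retinoblastoma-family genes (-0.16 and 0.04).

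In total 4615 genes passed, 2406 higher and 2209 lower, of which 464 and 318 changed at least 2-fold. Of these calls, 4517 had 1 sign on all 4 arrays, and the clones correlated at r = 0.682 across genes. A fit that models the shared RNAs called 472 of these genes, the comparison fitted alone called 246 genes, and 4693 or 2323 passed without the 27G5 or the 27H10 ratio.

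The third comparison asked the same of cells labelled as overexpressing Dnmt3a and Dnmt3b. The same placental hormones were among the highest genes: Prl2a1 rose by 4.77 ± 0.41, Prl2c5 by 4.69 ± 0.09, Prl2c3 by 4.67 ± 0.03 and Prl3d2 by 3.56 ± 0.66 (3.51 to 5.36 over the scalings). Their Dicer-null signals were, for Prl2a1, Prl2c3 and Prl3d2, well above background on 1, 3 and 3 of 4 arrays, and the 3 probes of Prl2c3 ranged from 2.03 to 4.67. The interferon-inducible Oasl1 and Psmb8 rose by 1.49 ± 0.03 and 1.42 ± 0.06. Dnmt3b fell by -1.04 ± 0.59 (adjusted p = 0.0342, a call lost under 4 alternatives, among them both left-out ratios, with adjusted p = 0.250 and 0.0729). Dnmt3a was at -1.03 ± 0.92 without passing (adjusted p = 0.0828), but passed as lower under 4 alternatives. Its clones were at -0.38 (27G5) and -1.68 (27H10) and its other probes at 0.20 and -0.72, so neither signal was called higher in the cells labelled as overexpressing them.

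Sct rose by 3.98 ± 0.03, Rhox6 by 3.55 ± 0.37, Exoc3l4 by 2.92 ± 0.11, Shroom1 by 2.85 ± 0.39 and Rhox9 by 2.78 ± 0.27. Alox12e fell by -2.75 ± 0.24, Dcn by -2.52 ± 0.15 (-4.23 to -2.46 over the scalings), Klk1b5 by -2.33 ± 0.02, Aass by -2.31 ± 0.33 and Edn2 by -2.25 ± 0.65. Ucma, Scd2, the ephrin receptor Epha4 and Nsg2 fell by -2.07 ± 0.03, -2.03 ± 0.32, -2.02 ± 0.02 and -2.01 ± 0.01. Dicer1 fell by -0.77 ± 0.08 (adjusted p = 0.00491), a call lost under 3 of 19 alternatives. Rbl2 fell by -0.37 ± 0.08 (adjusted p = 0.0450; -0.14 at its second probe), a call lost under 10 of 19 alternatives, and Dnmt1, at 0.27 ± 0.07, did not pass (adjusted p = 0.113).

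Of trophoblast markers, 9 of 12 rose, 0 fell and 3 did not pass, as when adjusted over the list alone. The median was 1.52 (adjusted p = 4.85e-06; adjusted p = 0.716 with an estimated correlation). Krt7 rose by 2.72 ± 0.05, Csh1 by 2.35 ± 0.37, Gata3 by 2.26 ± 0.08 and Cdx2 by 0.80 ± 0.18. Of interferon and MHC class I genes, 11 of 24 rose, 0 fell and 13 did not pass (15 and 0 when adjusted over the list alone). The median was 0.55 (adjusted p = 0.000131; adjusted p = 0.716 with an estimated correlation). Oasl2 rose by 1.36 ± 0.00, Usp18 by 1.25 ± 0.33 (1.21 to 3.18 over the scalings) and the RNA sensor Ifih1 by 0.99 ± 0.24 (0.97 to 1.52). Of germline genes, 5 of 24 rose, 2 fell and 17 did not pass (7 and 2 when adjusted over the list alone). The median was 0.22 (adjusted p = 0.0358; adjusted p = 0.866 with an estimated correlation). This call was lost with fry (adjusted p = 0.0820) and without the 27G5 ratio (median 0.16, adjusted p = 0.273), while the median was 0.44 without the 27H10 ratio. Stra8 rose by 1.58 ± 0.35 and Taf7l by 1.52 ± 0.14, and Hormad1 fell by -0.44 ± 0.12 (-0.04 at its second probe). The other members that rose were Rhox5, Rhox6 and Rhox9, all of the Rhox family. Of p53 targets, 6 of 21 fell, 1 rose and 14 did not pass (9 and 1 when adjusted over the list alone). The median was -0.38 (adjusted p = 0.00374; adjusted p = 0.866 with an estimated correlation). This call was lost with fry (adjusted p = 0.133) and without the 27H10 ratio (adjusted p = 0.0741). Zmat3 fell by -0.62 ± 0.02 and Gadd45a, a growth-arrest gene, rose by 0.90 ± 0.38.

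**Figure D2:**
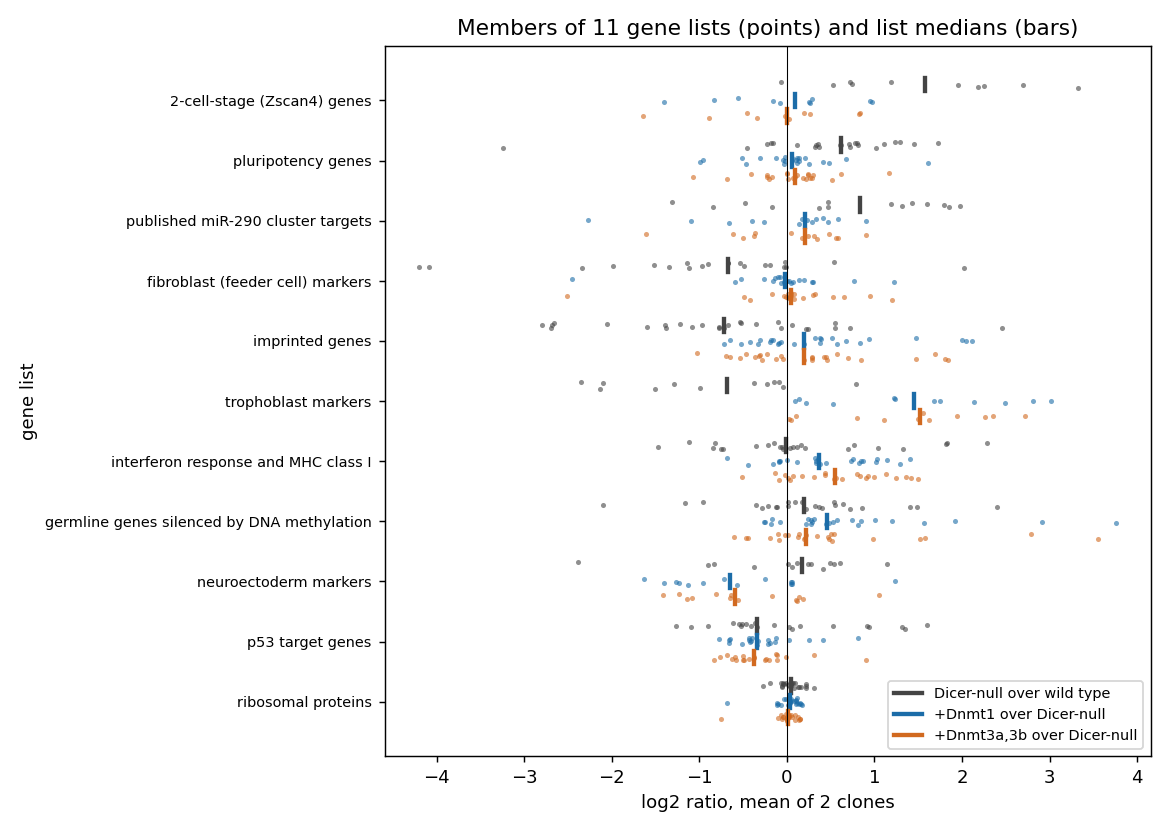
Log2 ratios of the measured members (points) and medians (bars) of 11 gene lists in the 3 comparisons with a reference. The trophoblast medians are -0.68 over wild type and 1.46 and 1.52 in the cells labelled as overexpressing Dnmt1 and Dnmt3a with Dnmt3b.

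Neuroectoderm markers, 6 of 14 lower, 1 higher and 7 not passing (8 and 1 when adjusted over the list alone), had a median of -0.60 that did not pass camera (adjusted p = 0.10, but 0.0460 with the stricter filter on dim probes and 0.0327 with fry), with Map2 at -1.24 ± 0.25 and Otx2 at -1.13 ± 0.08. Fibroblast markers, 3 higher, 2 lower and 16 not passing (3 and 3 when adjusted over the list alone), did not pass either (median 0.05, adjusted p = 0.713). Among imprinted genes, 5 of 27 rose and 3 fell, as when adjusted over the list alone (adjusted p = 0.713, but 0.0279 with fry), with H19 at 1.84 ± 0.20, Cdkn1c at 1.81 ± 0.20 and Igf2 at 1.69 ± 0.31. The mitosis genes Mki67, Cenpe and Cenpf fell by -1.03 ± 0.22, -1.03 ± 0.32 (probes from -1.40 to -0.86) and -0.88 ± 0.09 (-1.41 to -0.84 over the scalings), while 22 of 25 replication and mitosis genes did not pass. Their median was -0.03 (adjusted p = 0.324), -0.13 without the 27G5 ratio (adjusted p = 0.0449), and 0.00 without the 27H10 ratio (adjusted p = 0.797). It was 0.02 with the deposited log ratios and with the series value table. The glycolysis list (2 of 21 rose, as when adjusted over the list alone; adjusted p = 0.193) had a median of 0.17. It passed without the 27H10 ratio (0.24, adjusted p = 0.0128) and was at -0.00 without the 27G5 ratio (adjusted p = 0.842). Its member Vegfa, an angiogenic factor, rose by 1.30 ± 0.02 (its 3 probes ranged from 0.54 to 1.30). Rif1 fell by -1.16 ± 0.03, Terf2, which binds telomere repeats, by -0.34 ± 0.06 (its 4 probes ranged from -0.34 to 0.70; the call was lost under 9 of 19 alternatives, with a change of sign in 1), and Hmga2 by -0.69 ± 0.01 (probes from -0.74 to -0.34). Suv39h1 rose by 0.96 ± 0.16, while 2 of the 17 heterochromatin and Polycomb regulators fell (median -0.06, adjusted p = 0.551). Of Y-linked genes, 8 of 12 fell and 0 rose, with a median of -0.56 (-1.29 to -0.55 over the scalings; unadjusted camera p = 2.53e-06, and just under 0.05, also unadjusted, with an estimated correlation). The median and mean differed in sign for 2-cell-stage (0.00 and -0.12), mesoderm (0.03 and -0.00) and ribosomal protein genes (0.01 and -0.01).

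In total 4257 genes passed, 2093 higher and 2164 lower, of which 374 and 335 changed at least 2-fold. Of these calls, 4032 had 1 sign on all 4 arrays, and the clones correlated at r = 0.818. A fit that models the shared RNAs called 384 of these genes, and 4 or 0 genes passed with limma without the 27G5 or the 27H10 ratio, when the lone ratio is assumed to vary like those of the other comparisons.

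Set beside each other, the conditions labelled as overexpressing shared most of their calls. Both had 1776 genes called higher, where independence would give 251, and 1704 called lower (238 with independence). In opposite directions 0 genes were called. Both comparisons have the Dicer-null RNA of a clone as denominator, so part of the overlap can come from that RNA, and independence is not what unrelated effects would give. Across clones, where the ratios share no RNA, the conditions correlated at r = 0.784 across genes (0.759 and 0.809), and within clones at 0.869. Shared RNA alone gave 0.495 in simulation without any effect, which cannot be set beside these on the correlation scale. The covariance was 0.194 within and 0.174 across clones, a difference of 0.0196, while shared RNA alone gave 0.0352 in simulation. In the test of the difference, 0 genes passed with limma and 190 had an unadjusted p under 0.05. Differences taken within clones gave 0 and 213, and slide, which is also the clone here, as a fixed block gave 0 and 347. Chance alone would give 1003, so these tests were conservative, and a count of 0 does not show that the conditions are equal. Some differences were alike in both clones, and the largest, none of which passed (adjusted p = 1.00 for each), were Ccn4, a Wnt-induced matrix protein, at 1.02 ± 0.01, Prss23 at 0.81 ± 0.29, Egr2 at 0.74 ± 0.02, Zic2 at 0.72 ± 0.11 and Tagln at 0.66 ± 0.03 (label Dnmt3a and Dnmt3b over label Dnmt1). In the other direction lay the kinesin Kifc5b at -0.99 ± 0.11, the germ-cell gene Dazl at -0.90 ± 0.22, C130006E23 at -0.84 ± 0.10, Elf2 at -0.82 ± 0.27 and Mfap3l at -0.77 ± 0.24.

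**Figure D3:**
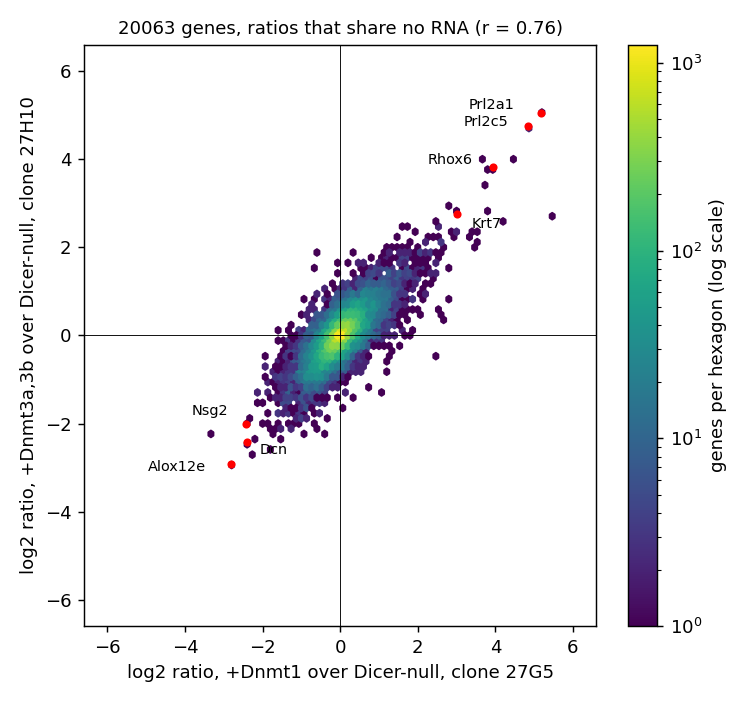
Log2 ratio over Dicer-null cells of the cells labelled as overexpressing Dnmt1 in clone 27G5 (x axis) and of those labelled as overexpressing Dnmt3a and Dnmt3b in clone 27H10 (y axis). Colour gives the number of genes per hexagon on a log scale, for 20063 genes, and some named genes are drawn as red points. These ratios share no RNA and correlate at r = 0.759 across genes, with Prl2a1 and Prl2c5 high and Alox12e and Dcn low on both axes.

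Some genes moved in opposite directions over wild type and over Dicer-null cells. Krt7, Krt18 and Igf2 were lower in Dicer-null than in wild-type cells and higher in both conditions labelled as overexpressing, while Alox12e, Dcn and Lefty2 went the other way. Of genes higher over wild type, 937 were lower in cells labelled Dnmt1 (450 with independence) and 894 in cells labelled Dnmt3a and Dnmt3b (441), and of genes lower over wild type, 883 and 794 were higher (483 and 420). Same-direction calls numbered 464 and 339 for the label Dnmt1 (490 and 443 with independence) and 387 and 315 for the label Dnmt3a and Dnmt3b (426 and 434). Across clones the ratios over wild type correlated with those of cells labelled Dnmt1 at r = -0.213 (-0.142 and -0.284) and of cells labelled Dnmt3a and Dnmt3b at r = -0.216 (-0.167 and -0.265). Within clones, where the Dicer-null RNA stands on both sides with opposite sign, the values were -0.219 and -0.230. Shared RNA alone gave -0.498 and -0.503 in simulation, which holds for ratios without any effect and cannot be set beside these on the correlation scale. The covariances were -0.0707 and -0.0691 within clones and -0.0677 and -0.0651 across clones, where no RNA is shared. The covariance within clones was thus lower than across clones by -0.00295 and -0.00407, while shared RNA alone gave -0.0360 and -0.0361 in simulation. A part of the excess of opposite calls can come from that shared RNA, but most of the negative covariance was also there where no RNA was shared.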

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

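The tests in this part were chosen after the results were seen, apart from those of exchanged channels and of saturated signals. The spike-in probe E1A_r60_a22, which no comparison used, had a red over green log2 ratio of 3.08 (SD 0.22, 2.75 to 3.42) on 12 arrays, a signal outside the main measurement. It was the highest of 10 spike-ins, whose means reached down to -2.75 (E1A_r60_n9) and whose SDs were 0.18 to 0.26. The median of E1A_r60_a22 was 3.13 in one dye orientation and 3.08 in the other, so its ratio followed the channel and not the cells. Among 299 named gene results, 0 had clones that moved in opposite directions on all of their arrays, a difference that was not tested further.

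Lower fibroblast markers in Dicer-null cells were set against feeder fibroblasts in the wild-type culture. In the whole list, 8 of 21 markers were not called lower and 2 of them rose, and feeder RNA in the reference would not give those 2 rises. The count does not decide the rest, since feeder RNA need not lower every marker. For the 13 members that fell, with a median of -1.14, feeder fibroblasts remain possible. Their SD of 1.24 across members does not decide it, since the fall also depends on how strongly the stem cells express each gene. Other expression of these genes by the stem cells cannot be told apart from feeder RNA. No biological explanation was tested.

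The alike profiles of the conditions labelled as overexpressing were set against the Dicer-null RNA shared within a clone, which the lower cross-clone correlation, 0.759 with no shared RNA, argued against. Gene-specific dye effects were argued against by correlations of 0.608, 0.443, 0.409 and 0.480 between arrays of opposite dye orientation and different clones. Steps common to making both lines labelled as overexpressing may explain them and stay open: 190 genes had an unadjusted p under 0.05 between the conditions, fewer than the 1003 that chance gives, so the test was conservative, and no vector-only line is among the labels. A shared action of the methyltransferases stays open too, as untested.

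The signals of Dnmt1, Dnmt3a and Dnmt3b, not called higher in the cells labelled as overexpressing them (although Dnmt1 passed without the 27G5 ratio, at 0.43 with adjusted p = 0.0390, which was from 0.0866 to 0.541 in the other alternatives), were set against exchanged channels. At least 99.5% of strongly changed genes lay closer to the channel labelled as Dicer-null in every clone and condition, which argued against that. Saturated signals were argued against because 0 of 8 overexpression arrays had a saturated methyltransferase probe. Probes outside the transcribed part of the introduced genes may explain the pattern and stay open, since 0 probes were at least 2-fold higher in their own condition and the introduced sequences are not given in the sources used here. An absence of overexpression in these RNAs stays open as well, as untested.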

How the results depend on the processing

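The number of calls depended on how the spread was modelled. With the shared RNAs modelled, 1945, 472 and 384 genes passed for Dicer-null over wild type, label Dnmt1 and label Dnmt3a with Dnmt3b, and a log2 ratio of at least 1 left 2114, 782 and 709, by its own construction. The Dnmt1 comparison fitted alone gave 246. For Dnmt3a with Dnmt3b, 12 arrays with a replicate block, which adds a gene-specific term for dye orientation, gave 6414. Leaving out a ratio, with the lone ratio assumed to vary like the others, gave 3121 to 3482, 2323 to 4693 and 0 to 4 genes. The cross-clone correlation of the wild-type and the Dnmt3a with Dnmt3b comparison was -0.299 among genes called over wild type, and that of the conditions labelled as overexpressing 0.831 among them and 0.725 with Spearman. Of the 15 gene list calls, 0 held with an estimated correlation, 12 with fry (which called 21, of them 9 that camera did not) and 14 or 15 in the leave-one-out fits, and each was kept under the other alternatives. Results that changed sign and were called in either fit were ribosomal proteins for label Dnmt1 under median centring (-0.11) and Terf2 for label Dnmt3a with Dnmt3b as the mean of all probes (0.13) (cause not tested). In all, 44 list medians changed sign, 0 of them of lists called in the main values. The remaining alternatives kept the counts within 1.5 times, 15 for wild type, 15 for Dnmt1 and 14 for Dnmt3a with Dnmt3b, and the 0 calls between these conditions held in 21. Of other results, list calls were the same in 717 cases, newly passing in 17 and no longer passing in 21, and named gene calls in 5229, 65 and 573. Of 269 called values of named genes, 176 lost the call under at least 1 alternative (116 with shared RNAs modelled), and 22 moved over 1.5 times under a scaling, 0 with a change of sign. Signal near background limits the fold of dim genes.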

Other observations

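These values were chosen after the data were seen. Of 396 groups of genes sharing a symbol stem, 9 passed camera in 1188 tests with the preset correlation. With an estimated correlation, a test on 3 residual degrees of freedom here, 0 of them passed (adjusted p = 0.986 for each), and with fry all 9 did, among 245. The 2'-5' oligoadenylate synthetases, sensors of double-stranded RNA, rose in Dicer-null cells: all 9 Oas genes passed, with a median of 1.67 (adjusted p = 2.85e-05), Oas1f at 2.48 ± 0.03 and Oas2 at 2.46 ± 0.32. Pramel genes, active in early embryos, rose at 7 of 8 (median 1.31, adjusted p = 0.0496), with Pramel37 at 2.06 ± 0.00, and histone demethylases of the Kdm stem at 10 of 16 (median 0.39, adjusted p = 0.0496), with Kdm3a at 1.19 ± 0.03. Of 18 genes of the Mapk stem, kinases and proteins that bind them, 9 fell (median -0.41, adjusted p = 0.0496), with the kinase Mapk12 at -1.26 ± 0.12. Prolactin-family genes rose at 8 of 10 in cells labelled as overexpressing Dnmt1 (median 2.28, adjusted p = 2.63e-05) and at 8 of 10 in cells labelled as overexpressing Dnmt3a and Dnmt3b (median 2.03, adjusted p = 1.87e-05). In cells labelled Dnmt1, 3 of 6 Rhox genes rose (median 1.24, adjusted p = 0.0366), as did 8 of 21 genes of the St stem, mostly sialyltransferases (median 0.35, adjusted p = 0.0496), with St6gal1 at 1.39 ± 0.29. Neither stem passed in cells labelled Dnmt3a and Dnmt3b, but the same 3 Rhox genes rose there (Rhox5 0.98, Rhox6 3.55 and Rhox9 2.78), and St6gal1 was at 1.47 ± 0.06. Those Rhox genes are also on the list of germline genes, so their rise is counted there too. Of 297 zinc finger genes of the Zfp stem, 80 fell and 16 rose in cells labelled Dnmt3a and Dnmt3b (median -0.11, adjusted p = 0.00720). None of these medians changed sign over the scalings (0 groups), but their size did: the Prl medians ran from 2.22 to 5.48 and from 1.99 to 5.31, that of Oas from 1.54 to 2.26, of Pramel from 1.21 to 2.16, of Kdm from 0.36 to 0.58 and of Zfp from -0.16 to -0.05.

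Over wild type, the clones differed along 2 chromosomes (build mm7). Genes of chromosome 11 (1643 genes) had medians of 0.16 in clone 27G5 and -0.00 in clone 27H10, a median difference of 0.20 (0.18 to 0.28 over the scalings), and 80.7% were higher in 27G5. On chromosome 6 (1017 genes) the median difference was 0.10 (0.09 to 0.18) and lay in the part from position 85476768 on, with 0.27 and 0.20 in its stretches against -0.02 and 0.01 before it. On the other 18 chromosomes, Y aside, it lay between -0.04 and 0.03. Over Dicer-null cells the differences on chromosomes 6 and 11 were 0.10 (0.09 to 0.18 over the scalings) and 0.04 (-0.01 to 0.07, so its sign changed) for the label Dnmt1, and 0.08 (0.07 to 0.12) and 0.06 (0.06 to 0.09) for the label Dnmt3a and Dnmt3b, against -0.04 to 0.05 and -0.02 to 0.02 on the other 18. Of Y-linked genes, Ddx3y fell by -1.74 ± 0.61 in cells labelled Dnmt1 and -1.67 ± 0.51 in cells labelled Dnmt3a and Dnmt3b, and rose by 1.09 ± 0.12 over wild type. The 2 arrays of the 27G5 pair labelled Dnmt3a and Dnmt3b matched each other at r = 0.396, against 0.673 to 0.910 in the other pairs. With the dye term removed the values were 0.836 against 0.956 to 0.982, so much of the mismatch went with gene-specific dye effects.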
